A study of Mus musculus with 6 samples.

How the data were processed

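Adult muscle stem cells, the Pax7-expressing cells from which skeletal muscle regenerates, were taken from female C57BL/6J mice aged 6 to 8 weeks and expanded on Matrigel for 2 days, per the labels' protocols. The cultures then spent 6 h in serum-free medium with a soluble BMP receptor, ALK3-Fc at 200 ng/ml, which binds BMPs left over from serum. A pulse of 100 ng/ml BMP6, or of the solvent without BMP6, followed for 1 h. Total RNA was converted to biotin-labelled sense-strand cDNA with an Affymetrix whole-transcript kit and hybridised to arrays. The array type is not given in the sources used here. The 6 samples were 3 BMP6 and 3 vehicle cultures, 1 array each.

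The deposited values were log2 expression values, 1 per probe set and array, which the authors made with RMA in the oligo package, per the submitters' processing notes. RMA subtracts background, sets all arrays to a common distribution and summarises the probes of a probe set. Versions, settings and the source of the gene annotation are not given in the sources used here. The 2 deposited tables, 1 with gene symbols and 1 without, differed by at most 5e-09 at any value. Array medians lay between 6.02 and 6.10, and pairs of arrays correlated at 0.994 to 0.997 across probe sets. Because RMA forces arrays to a common distribution, a shift shared by most transcripts would not be seen, and log2 differences of dim probe sets are compressed. Arrays carry no read depth, so their number limits the precision, and no detection p-value or background level was given that would mark a probe set as unexpressed.

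Of the 34760 probe sets, 21893 carried a gene symbol and 12867 did not. The latter were kept out of the comparison and tested separately. Where a gene had several probe sets (907 genes), the one with the highest mean over all 6 arrays was used, which set 1730 aside and left 20163 genes. Control probe sets were not used, and no filter on dim probe sets was applied. Symbols were those of the deposited table. A RefSeq gene table of the GRCm38.p6 assembly, used only to check names, held the Entrez identifiers of 21812 probe sets and gave the same symbol for 20292 of them (93%). The files name no genome build, so no coordinates are given.

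BMP6 was compared with vehicle by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, a two-sided moderated test), with all 6 arrays, no covariate, and Benjamini-Hochberg adjustment over the 20163 genes. A gene was called at an adjusted p under 0.05. The fit left 4 residual degrees of freedom, to which eBayes added 5.72 from the other genes. Standard errors and 95% intervals of log2 fold changes are those of the moderated test, and SDs are over the 3 samples of a group. The 20 gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 20 lists, with camera at an estimated correlation and fry as alternatives. Camera asks whether a list moved against the other genes. Fry asks whether its members moved on balance one way, and its mixed p whether any changed in either direction, which a few strongly changed members can carry. For single list members, adjustment over the list alone is given beside adjustment over all genes.

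The design, the tests, the gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took, among genes past the threshold whose 3 values in 1 group all lay above the 3 of the other, the 15 with the largest rise and the 10 with the largest fall. It added 16 genes of BMP and Notch signalling and of muscle stem cells whatever their result. It also added up to 4 members of each list, those past the threshold in order of p, or the 1 or 2 members with the lowest p where none passed. This gave 53 genes. Other genes are marked where they were chosen after their values were seen. The lists covered BMP targets and feedback, BMP ligands, receptors and SMADs, Notch targets, Notch receptors, ligands and machinery, muscle stem cell and quiescence genes, myogenic commitment and differentiation, osteogenic and chondrogenic genes, both phases of the cell cycle, immediate early genes, TGF-beta targets, Wnt targets, NF-kB and inflammatory genes, heat shock and unfolded protein stress, and cholesterol synthesis. The remaining 5 held markers of endothelial, immune, fibro-adipogenic, pericyte and Schwann cells, which dissociated muscle can also hold. A few listed symbols had no probe set under that name, most of them old names of a gene also listed under its current one. Foxm1 and Rnf43 were among those not measured.

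The labels call the samples biological replicates 1, 2 and 3 of each treatment. The source names give mice 1, 2 and 3 to the BMP6 samples but mice 1, 2 and 2 to the vehicle samples, so that the third vehicle sample carries the number 3 in its title and mouse 2 in its source name. In the column headers each pair of samples with the same replicate number shares 1 code, the third pair included, beside a number particular to each array. The headers do not say what the shared code stands for. Numbers were therefore taken as marking cells of 1 mouse, split between the treatments, with the third pair uncertain. Deviations from the group means over all genes correlated at 0.32, 0.05 and 0.43 for replicates 1, 2 and 3, against 0.02 for the third vehicle sample and BMP6 replicate 2. Pairs of different numbers ran from -0.44 to 0.18. The highest of them, BMP6 replicate 1 with vehicle replicate 2, lay above the pair of number 2. The consensus correlation within a number was 0.27. Replicate number was used as a fixed and as a random block among the alternatives, as was the mouse in the source names. If the third vehicle sample did come from mouse 2, the vehicle group held 2 mice, and its spread would partly be that between cultures of 1 animal. Differences between replicate numbers were tested with limma's F-test in a fit that also held the treatment.

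The alternatives further covered filters on dim genes, other normalisations of the deposited values, the other table, the mean of a gene's probe sets, an intensity-trended robust prior, array weights, other thresholds and leaving out each array. Leaving out the third pair and testing all probe sets together were added after seeing the data. The procedure was tested on simulated data for the 20163 genes, each with its moderated variance. With 20 changed genes in each of 20 runs, 79 of 80 rises and 60 of 60 falls of log2 1 were recovered, and 42 of 80 rises and 37 of 60 falls of log2 0.5. Of 402860 unchanged genes 39 were called. In 40 simulated runs in which 1 list was raised by 0.3, camera called it in 40, and called 4 of 760 unchanged lists. The simulated genes varied independently of each other, which genes of a list in cells do not.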

Results

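Expression was measured on arrays in cultured adult mouse muscle stem cells after a 1 h pulse of 100 ng/ml BMP6, a bone morphogenetic protein that signals through SMAD1, SMAD5 and SMAD9, or of vehicle. There were 3 arrays in each group and 20163 genes with a symbol. Serum and residual BMPs had been withdrawn for 6 h before the pulse, so the comparison asks which transcripts responded within 1 h, and in particular whether genes of the Notch pathway were among them, the purpose that the series title gives. Values are log2 RMA expression, and a difference of 1 on this scale is a 2-fold difference.

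With BMP6, 17 genes were called higher, and no gene was called lower. The largest rise was that of Dlx2, a homeobox transcription factor, at 3.93-fold (95% interval 3.05 to 5.06; log2 fold change 1.97, SE 0.16, limma adjusted p = 0.00138). It was followed by Hes1, a transcriptional repressor best known as a Notch target, at 3.38-fold (2.81 to 4.05), and by Smad7, an inhibitory SMAD that shuts off the receptors of the pathway, at 3.30-fold (2.91 to 3.75). Id1 and Id3, which bind and inactivate bHLH transcription factors such as MyoD, rose 2.99-fold (2.58 to 3.46) and 2.88-fold (2.32 to 3.56). Skil, a co-repressor of SMAD proteins, rose 2.77-fold, Klf10, a zinc-finger repressor, 2.47-fold, and Snai1, the repressor known from epithelial-mesenchymal transition, 2.40-fold.

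These 8 genes made up the calls of 2-fold or more. The other 9 rose between 1.55-fold and 1.92-fold. They were Smad6, Nfkbia, Atoh8, Ccn1, Dusp1, Pwwp2b, Pmepa1, Cxcr4 and Gadd45b, the last of which lies outside the naming rule and was chosen after its values were seen. Each of the 17 was higher in all 3 BMP6 samples than in any vehicle sample. Over all genes, 1554 (7.71%) had groups that did not overlap, where chance gives 10%. Within replicates 1, 2 and 3, the 17 genes were higher in BMP6 by 1.22, 1.20 and 1.03 on average on the log2 scale. Each was higher in 3 of 3 pairs, which follows from groups that do not overlap. The median log2 fold change of all genes was -0.0013.

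**Figure D1:**
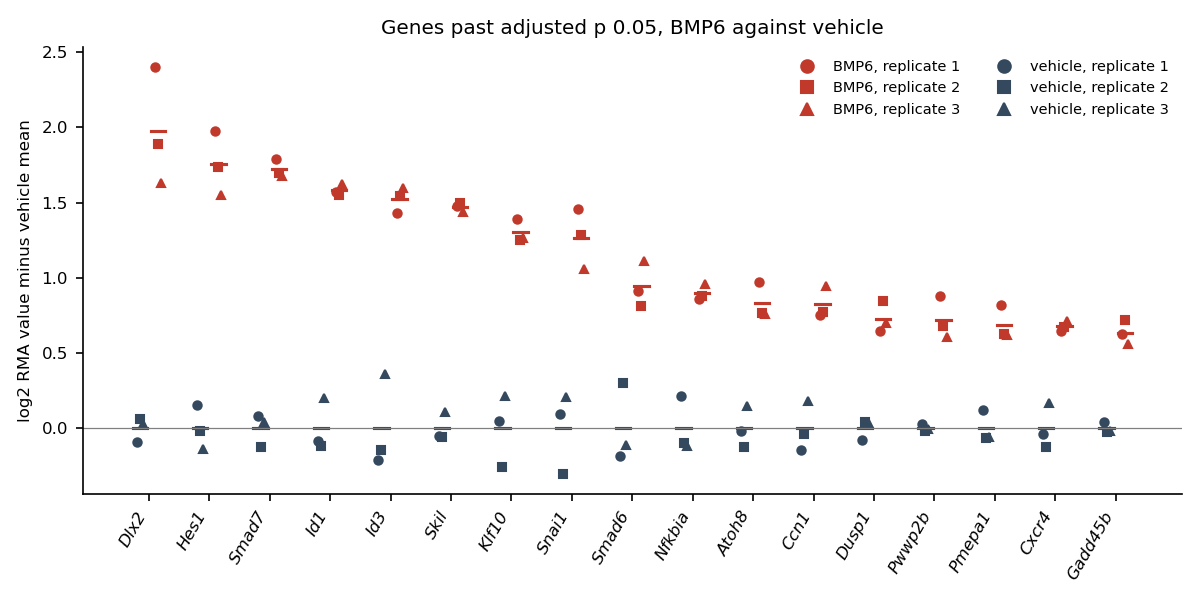
Log2 RMA value of each sample minus the vehicle mean of that gene, for the 17 genes past adjusted p 0.05, ordered by their rise. Symbols stand for replicates and short lines for the means of 3 samples. BMP6 and vehicle samples do not overlap for any of these genes, from Dlx2 at a mean of 1.97 to Gadd45b at 0.64.

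At an unadjusted p under 0.05 there were 639 genes, 283 higher and 356 lower, and at an unadjusted p under 0.001 there were 36, all higher. With replicate number as a block limma called 29 genes, the same 17 among them, and of the 12 added only Clec2d, the ligand of an inhibitory natural killer cell receptor, was lower (log2 fold change -0.80, blocked adjusted p = 0.0141; adjusted p = 0.918 without the block; chosen after its values were seen). Clec2d passed under this alternative alone, and not with the random block or without the third pair. Without BMP6 replicate 1 the count was 10, without BMP6 replicate 2 it was 7, and without vehicle replicate 1 or vehicle replicate 2 it was 9. Smad7, Skil, Id1, Hes1, Dlx2, Klf10 and Id3 passed each time 1 array was left out, while Smad6, which had an adjusted p of 0.0403, did not pass in 10 of the 21 alternatives. With the mouse of the source names as a fixed block, Ccn1, Cxcr4, Gadd45b and Smad6 did not pass.

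Direct targets and feedback regulators of BMP signalling formed the list with the clearest shift. Of its 26 measured genes, 7 were called higher and none lower over all genes tested, with 13 higher when adjusted over the list alone. Smad7 stood at 9.02 ± 0.06 in BMP6 and 7.30 ± 0.11 in vehicle (mean ± SD, n = 3), Id1 at 11.30 ± 0.04 and 9.72 ± 0.17, Id3 at 10.39 ± 0.09 and 8.86 ± 0.31, and Skil at 9.60 ± 0.03 and 8.13 ± 0.10. Klf10, Smad6, which blocks BMP-receptor signalling to SMADs, and the bHLH factor Atoh8 (1.78-fold, adjusted p = 0.0128) were the other three. Id2 stood 1.39-fold above vehicle (log2 fold change 0.47, SE 0.10) and did not pass over all genes (adjusted p = 0.567).

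The median log2 fold change of this list was 0.29, and camera with its preset correlation placed it above the other genes (adjusted p = 3.13e-24). The adjusted p was 0.0971 with an estimated correlation, and 0.0126 by fry (0.0949 with the replicate block). The list of BMP ligands, receptors and SMADs held 25 genes, extracellular regulators such as Chrd and Bmper among them, but not Smad9. In this list 0 passed in limma, 0 had an unadjusted p under 0.05, and camera gave an adjusted p of 0.752. Its members nearest to a call were Bmp4 (log2 fold change -0.17, SE 0.08) and Rgma, a BMP co-receptor (-0.20, SE 0.11). Smad9 had been placed in the target list and stood at 0.46 (SE 0.08, chosen after its values were seen). It was higher when adjusted over that list alone, and did not pass over all genes (limma adjusted p = 0.166).

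**Figure D2:**
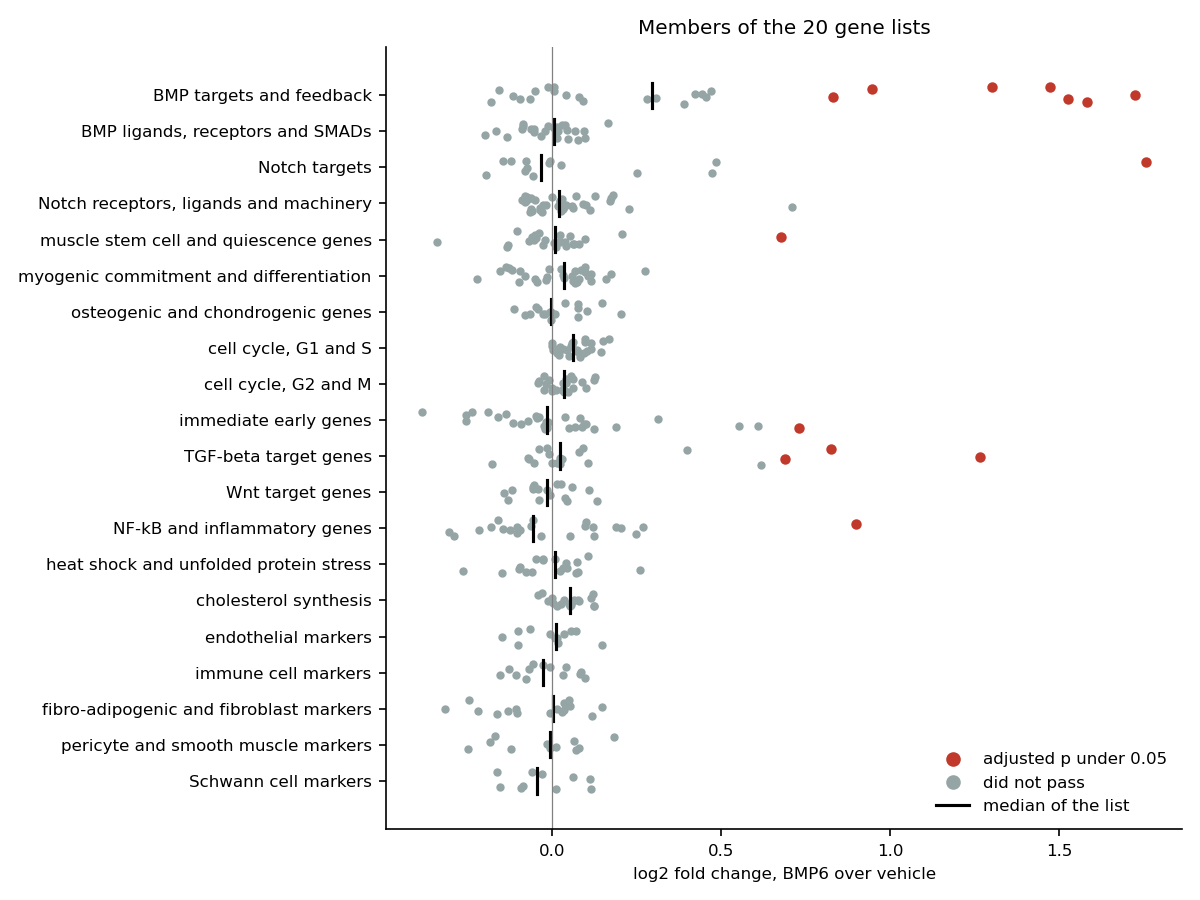
Log2 fold change of BMP6 over vehicle for each measured member of the 20 gene lists, 1 point per gene. Red points passed adjusted p 0.05 over all genes, grey points did not, and black bars mark list medians. The BMP target list has 7 red points and a median of 0.29, and the other lists have between 0 and 3 red points.

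Among Notch pathway genes, only Hes1 was called, and it was higher in BMP6. It stood at 9.06 ± 0.21 in BMP6 and 7.30 ± 0.15 in vehicle (n = 3), a log2 fold change of 1.76 (SE 0.12, limma adjusted p = 0.000255), with differences of 1.82, 1.75 and 1.69 within replicates 1, 2 and 3. Hey1, another Notch-induced repressor, which BMPs also induce in other cells, was measured at 1.40 times the vehicle level (95% interval 1.20 to 1.64; log2 fold change 0.49, SE 0.10) and was higher in all 3 BMP6 samples than in any vehicle sample. It did not pass over all genes (adjusted p = 0.449; 0.182 with the replicate block). Lfng, the glycosyltransferase that tunes the response of Notch receptors to their ligands, stood at 1.63 times vehicle (1.38 to 1.93) with an adjusted p of 0.0675. It passed with replicate number as a block (blocked adjusted p = 0.00690).

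Of the Notch targets not named in advance, Bhlhe40, a bHLH repressor, was measured at a log2 fold change of 0.47 (SE 0.08, adjusted p = 0.134) and Hes6 at 0.25 (SE 0.10, adjusted p = 1), both chosen after their values were seen. Among the Notch genes named in advance, the log2 fold change was -0.01 (SE 0.11) for Heyl, -0.06 (SE 0.11) for Nrarp, -0.12 (SE 0.10) for Notch3, 0.10 (SE 0.10) for Dll1 and -0.07 (SE 0.11) for Jag1. Nrarp was dim, at a mean of 5.18, where a change would be compressed. Notch1 was measured at 0.23 (SE 0.08) with an unadjusted limma p of 0.0184 and an adjusted p of 1.

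As groups, 1 of 14 Notch targets rose over all genes, and 3 (Hes1, Hey1 and Bhlhe40) were higher when adjusted over the list alone. The list's median log2 fold change was -0.03 and its mean 0.16, which differ in sign, and 5 of the 14 were positive. Camera gave an adjusted p of 0.137, in the upward direction of the mean, 0.194 with the replicate block and 0.00104 without BMP6 replicate 3. The list's mean deviation was lowest in replicate 3 in both treatments (-0.0332 in BMP6, -0.131 in vehicle). Leaving out only its BMP6 sample unbalances the replicate numbers, so that last p does not show an effect of BMP6. Fry gave 0.524 for a move in 1 direction and 0.000525 for changes in either direction. A strongly changed member such as Hes1 can carry the latter. Of the 38 Notch receptors, ligands and machinery genes, 0 passed over all genes in limma, 3 were higher at an unadjusted p under 0.05, 1 (Lfng) was higher when adjusted over the list alone, and camera gave an adjusted p of 0.208.

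**Figure D3:**
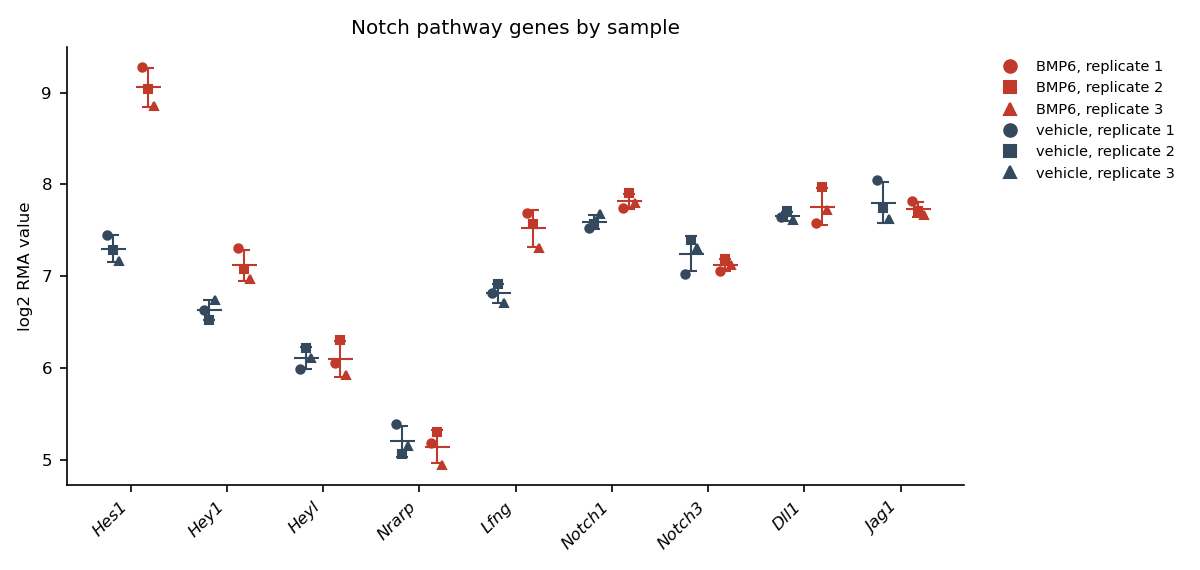
Log2 RMA values of the 6 samples for Hes1, Hey1, Heyl, Nrarp, Lfng, Notch1, Notch3, Dll1 and Jag1. Symbols stand for replicates, long horizontal lines for means and error bars for the SD of 3 samples. Hes1 lies at a mean of 9.06 in BMP6 and 7.30 in vehicle, while Heyl, Nrarp, Notch3, Dll1 and Jag1 overlap between the groups.

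Genes known as targets of TGF-beta, a related ligand that signals through SMAD2 and SMAD3, also held several of the calls. Of 20 measured, 3 rose: Snai1, from 7.39 ± 0.27 to 8.65 ± 0.20 (n = 3, adjusted p = 0.0115), Ccn1, a secreted matrix-associated protein, 1.77-fold (adjusted p = 0.0154), and Pmepa1, a membrane protein that restrains TGF-beta signalling, 1.61-fold (adjusted p = 0.0253). The count was 5 when adjusted over the list alone, and 4 over all genes with the replicate block, which added the bHLH repressor Bhlhe41 (log2 fold change 0.62, blocked adjusted p = 0.0209; chosen after its values were seen). The median of the list was 0.02, and camera placed it above the other genes (adjusted p = 2.16e-05; adjusted p = 0.505 with an estimated correlation, and 0.412 by fry, or 0.000362 for changes in either direction).

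Of 32 immediate early genes, which respond within minutes to many stimuli, 1 rose, the MAP kinase phosphatase Dusp1 (1.66-fold, 95% interval 1.46 to 1.88, adjusted p = 0.0115), and 3 were higher when adjusted over the list alone. With the replicate block 3 passed over all genes, Dusp1, the transcription factor Csrnp1 (log2 fold change 0.61, blocked adjusted p = 0.0133) and the AP-1 subunit Fosb (0.55, blocked adjusted p = 0.0143), the latter pair chosen after their values were seen. Of 23 NF-kB and inflammatory genes 1 rose, Nfkbia, the inhibitor of NF-kB, at 1.86-fold (1.60 to 2.17, adjusted p = 0.0115). Adjusted over the list alone, 2 were higher and 1 lower. Camera gave adjusted p values of 0.752 and 0.848 for these lists, whose medians (-0.02 and -0.06) and means (0.03 and 0.02) differed in sign. At an unadjusted p under 0.05 there were 8 immediate early genes, 4 higher and 4 lower, and 5 NF-kB and inflammatory genes, 3 higher and 2 lower. Fry's adjusted p for changes in either direction was 0.000494 and 0.000362. A strongly changed member such as Dusp1 or Nfkbia can carry this p, so it does not show a change across the list. Pwwp2b, a chromatin-associated protein in none of the lists, rose 1.65-fold (adjusted p = 0.0141).

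Muscle identity and differentiation genes held 1 call after 1 h of BMP6. Of 26 muscle stem cell and quiescence genes, Cxcr4, the receptor for the chemokine CXCL12, rose 1.60-fold (95% interval 1.39 to 1.83, adjusted p = 0.0257). Cxcr4 passed in 14 of 21 alternatives, and not with the mouse of the source names as a fixed block. Pax7, the defining transcription factor of these cells, had a log2 fold change of 0.10 (SE 0.07). Myf5, chosen after its values were seen, had one of -0.34 (SE 0.19, or 0.07 with the replicate block). It was lower in BMP6 within each pair and did not pass with or without the block (limma blocked adjusted p = 0.297). Myod1, the myogenic determination factor, was abundant in both groups, at 12.28 ± 0.03 in BMP6 and 12.12 ± 0.07 in vehicle (n = 3), and its log2 fold change of 0.16 (SE 0.07) did not pass (adjusted p = 1). None of the 31 commitment and differentiation genes passed in limma, and 1 had an unadjusted p under 0.05, Myf6 (log2 fold change -0.22, SE 0.07). Myog, the differentiation factor myogenin, had a log2 fold change of 0.04 with an SE of 0.48, or of 0.11 with the replicate block. It stood at 8.65, 8.33 and 6.85 in BMP6 replicates 1, 2 and 3 and at 8.75, 7.94 and 7.03 in the vehicle replicates. Camera gave adjusted p values of 0.650 and 0.752 for these lists, and 0.618 for differentiation with the replicate block. For differentiation it gave 1.83e-05 without BMP6 replicate 3 and 0.044 without vehicle replicate 1, both upward. As a mean deviation from the 6 arrays, that list lay at 0.389, 0.0939 and -0.455 in BMP6 replicates 1, 2 and 3. In the vehicle replicates it lay at 0.336, 0.0516 and -0.415. Leaving out 1 sample of a pair unbalances the replicate numbers, so the p values without 1 array do not show an effect of BMP6.

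**Figure D4:**
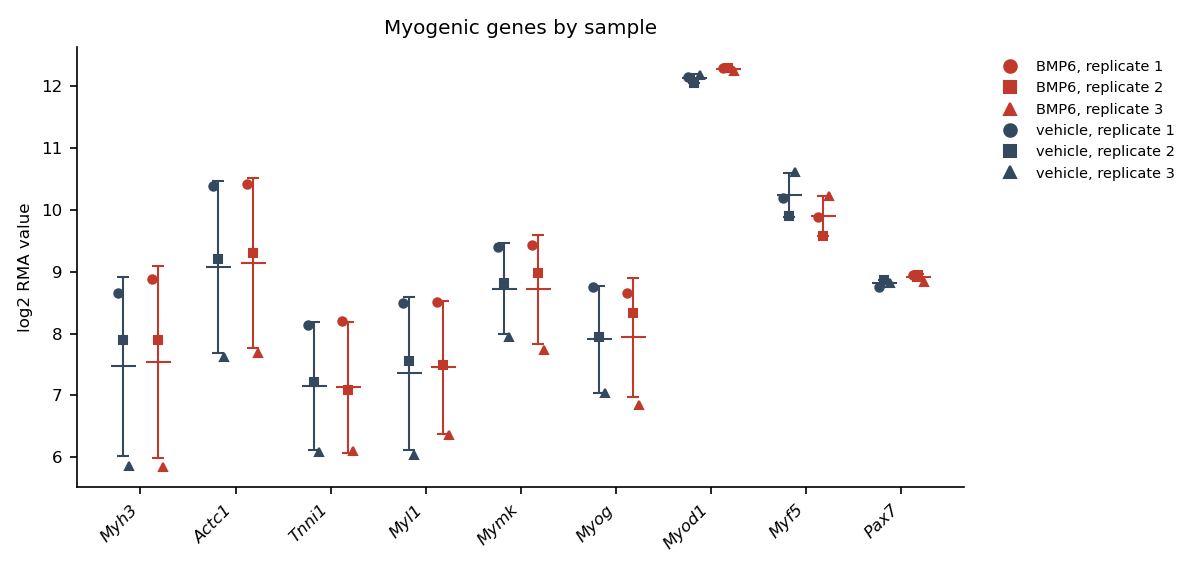
Log2 RMA values of the 6 samples for the differentiation genes Myh3, Actc1, Tnni1, Myl1, Mymk and Myog and for Myod1, Myf5 and Pax7. Symbols stand for replicates, long horizontal lines for means and error bars for the SD of 3 samples. Myog runs from 8.75 to 7.03 over the vehicle samples and from 8.65 to 6.85 over the BMP6 samples, while Pax7 lies between 8.75 and 8.94 in all 6.

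Osteogenic and chondrogenic genes, the fates that BMPs induce over days in mesenchymal cells, held no call. Of 18 measured, 0 passed in limma and 1 had an unadjusted p under 0.05, Sp7, the osteoblast transcription factor (log2 fold change 0.20, SE 0.08). The hypertrophic cartilage collagen Col10a1 was measured at 0.15 (SE 0.08), and camera gave an adjusted p of 0.666. Only 6 of the 18 lay above the median mean of all genes. Sp7 and Col10a1 averaged 5.47 and 5.15, and differences of dim probe sets are compressed. Of 17 Wnt targets 0 passed and 0 had an unadjusted p under 0.05, with a camera adjusted p of 0.752. Notum, a secreted Wnt inhibitor, was measured at -0.14 (SE 0.10) and the mesoderm factor T at -0.13 (SE 0.09). Of the 17 Wnt targets only 7 lay above the median mean, and T averaged 4.35, so the absence of calls says little about the dim members.

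The 26 G1 and S phase genes of the cell cycle were all slightly above vehicle, by a median of 0.06 on the log2 scale. None passed singly in limma over all genes or over the list alone, and 0 had an unadjusted p under 0.05. Cdk6, a kinase that drives entry into S phase, was measured at 0.17 (SE 0.08) and E2f1, a transcription factor of S phase genes, at 0.15 (SE 0.09). Camera placed the list above the other genes (adjusted p = 0.00350), with an adjusted p of 0.962 with an estimated correlation and 0.935 by fry. The preset-correlation adjusted p was 0.341 without BMP6 replicate 3, 0.152 without vehicle replicate 1 and 0.287 without vehicle replicate 2.

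Of 24 G2 and M phase genes 0 passed in limma and 0 had an unadjusted p under 0.05, with the mitotic kinase Ttk at 0.13 (SE 0.08) and Hmmr at 0.12 (SE 0.10). Camera gave the list an adjusted p of 0.208, or 0.00652 without BMP6 replicate 1 and 0.000685 without vehicle replicate 3. The counts were also 0 and 0 for the 19 cholesterol synthesis genes, where Fdps and Fdft1, enzymes of the pathway before and at squalene, both stood at 0.12 (SE 0.10 and 0.12). Their camera adjusted p was 0.208, or 0.000846, 0.0361 and 0.000641 without BMP6 replicate 1, BMP6 replicate 3 and vehicle replicate 2. For both lists the fits without 1 array left the replicate numbers unbalanced, so their p values do not show an effect of BMP6. Of 19 heat shock and unfolded protein genes 0 passed, and 2 had an unadjusted p under 0.05, the co-chaperone Bag3 at 0.26 (SE 0.08) and Chac1, a gene of the unfolded protein response, at -0.26 (SE 0.12). Camera gave an adjusted p of 0.819.

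Markers of other cells of muscle did not differ by a call between the treatments, but many of them were dim. Lyz2, Tek, Cd52 and Pecam1 averaged 4.60, 5.22, 5.57 and 5.59, where the array medians of the tested genes were 6.38 to 6.45. Above the median mean of all genes lay 7 fibro-adipogenic and 7 Schwann cell markers, and fewer than 5 of each other type. The absence of calls therefore says little about the dim markers. None of the 12 endothelial, 13 immune, 16 fibro-adipogenic, 11 pericyte or 10 Schwann cell markers passed in limma, over all genes or over their list alone. Camera gave adjusted p values of 0.974, 0.752, 0.404, 0.752 and 0.650 in that order. It gave 0.0361 for the fibro-adipogenic list without BMP6 replicate 3, a fit that leaves the replicate numbers unbalanced. An unadjusted p under 0.05 was found for 2 fibro-adipogenic markers, Clec3b (log2 fold change -0.25, SE 0.09) and Smoc2 (-0.16, SE 0.07), and for 2 pericyte markers, Synpo2 (-0.25, SE 0.09) and Cspg4 (0.18, SE 0.08). It was found for 0 markers of the other three types, where Pecam1 (-0.15) and Tek (0.15) led the endothelial list, Foxd3 (-0.16) and Mag (-0.15) the Schwann cell list, and Lyz2 (-0.15) and Cd52 (-0.13) the immune list.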

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

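The fits without the third pair and with all probe sets were chosen after seeing the data, the others before. With replicate number as a fixed block (the paired fit) limma called 29 genes, 28 higher and 1 lower, against 17 and 0 without it; Lfng was the only gene of the naming rule it moved past the threshold, it kept the 3 list calls of camera, and it changed no other call of those 53 genes. The count was 32 with a random block, 26 without the lowest tertile of genes by mean, 30 without genes below the median mean, 26 after centring arrays on their medians, 27 with a trended robust prior, 26 at an adjusted p of 0.1, 7 at 0.01 and 8 with a 2-fold minimum, all higher. Leaving out 1 array gave 7 to 15, the extremes without BMP6 replicate 2 (7) and without either sample of number 3 (15 each); it was 10 without BMP6 replicate 1 and 9 without vehicle replicate 1 or 2. With 2 samples in an arm and fewer residual degrees of freedom, lower counts follow from the construction. The block without the third pair called 22 genes, 15 of the 17 among them, and 2 were lower (Sh2d1b1 and Zfand1, not Clec2d; chosen after their values were seen). With all 34760 probe sets tested together 3 genes passed (Smad7, Skil and Id1), and Hes1 had an adjusted p of 0.0509; probe sets without a symbol had a median residual SD of 0.198 against 0.107 for the tested genes, and the prior degrees of freedom fell from 5.72 to 2.53. The mouse of the source names called 17 as a random block. As a fixed block it called 15, with 13 of the 17 among them. Ccn1, Cxcr4, Gadd45b and Smad6 were lost, and Lfng and Sik1 were added. Quantile normalisation and cyclic loess called 16 each, averaged probe sets 17, array weights 22, and the other table, which holds the same values, 17. For the other moved counts the cause was not tested.

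Camera called 3 lists, 0 with an estimated correlation and 1 by fry (BMP targets), and 3 to 6 with 1 array left out (5 without BMP6 replicate 1, 6 without BMP6 replicate 3). The estimated-correlation adjusted p was 0.0971 for BMP targets, 0.505 for TGF-beta targets and 0.962 for G1 and S genes; fry gave 0.412 and 0.935 for the last 2. Notch targets passed without genes below the median mean (0.00808). With 1 array left out, adjusted p ran from 0.00104 to 0.493 for Notch targets, 5.99e-06 to 0.341 for G1 and S, 0.000685 to 0.883 for G2 and M, 0.000641 to 0.432 for cholesterol synthesis, 0.0361 to 0.905 for fibro-adipogenic markers and 1.83e-05 to 0.786 for myogenic differentiation; BMP and TGF-beta targets passed in 6 of 6. The arrays behind each change are named with the list in the results.

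For the 53 named genes, 1024 of 1092 comparisons with 21 alternatives kept direction and side of the threshold, 58 lost the call, 10 gained it (all Lfng) and 0 reversed; genes past the threshold in neither fit were given no direction. Smad7, Skil and Id1 passed in 21 of 21; Hes1, Dlx2, Id3 and Klf10 failed only with all probe sets; Smad6 passed in 11 and Pmepa1 in 12. Background signal was not given, so which genes lay too near it to show a change is not known.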

Other observations

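The tests of gene counts across splits, of an array offset, of fewer muscle cells and of the third vehicle sample's mouse were chosen after the result was seen, and the others before. Differentiation genes of muscle, which showed no call between BMP6 and vehicle, differed widely between replicate numbers. In a limma fit that also held the treatment, 79 of 20163 genes differed between the numbers, 13 of the 31 myogenic differentiation genes among them, each highest in replicate 1. Myh3, the embryonic myosin heavy chain, averaged 8.77, 7.89 and 5.85 in replicates 1, 2 and 3 (2 samples each, adjusted p = 1.98e-06), cardiac actin Actc1 10.41, 9.25 and 7.66 (adjusted p = 1.98e-06), the fusion protein Mymk 9.42, 8.90 and 7.84, and Myog 8.70, 8.13 and 6.94 (adjusted p = 0.000913). The stem cell gene Myf5 averaged 10.04, 9.75 and 10.42 (adjusted p = 0.0295), Cd34 9.11, 8.20 and 8.77, and the growth factor receptor Fgfr4 8.41, 8.94 and 9.13. These genes were chosen after their values were seen.

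The differentiation list lay lower in replicate 3 than in replicate 1 by nearly as much in each treatment (mean difference -0.84 in BMP6 and -0.75 in vehicle). Fewer muscle cells in replicate 3 would lower stem cell genes too, and the muscle stem cell list differed by 0.0167 (BMP6) and 0.0673 (vehicle), which argues against this. A second list of 20 late muscle genes, not used before, differed between replicates 3 and 1 by -0.204 (BMP6) and -0.193 (vehicle), with 16 of 20 members lower in each, just short of the bound of -0.2 set in both treatments for different degrees of differentiation. Cultures that had differentiated to different degrees may account for the pattern, but this and a difference between the mice themselves, which was not tested, stay open. The differentiation list of the third vehicle sample lay -0.488 from the mean of the samples of number 2 and 0.0401 from the third BMP6 sample, while the vehicle samples of numbers 1 and 2 lay -0.0529 and -0.0423 from their partners. These values do not settle its mouse, since the list was noticed in a fit by replicate number and cultures of 1 mouse could differ in differentiation.

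All 17 called genes were higher in BMP6. An offset between the arrays of the groups would be removed by rescaling. Centring arrays on their medians called 26 genes, and quantile normalisation and cyclic loess 16 each, all higher. Over these the lowest log2 fold change of the 17 genes was 0.605 (SE 0.08), against 0.64 (SE 0.08) as deposited. RMA had already set the arrays to a common distribution, and the median log2 fold change of all genes was -0.0013 as deposited. Little offset was left to remove, so the rescalings could hardly lower these genes and do not decide the question. Smad6 and Pmepa1 lost their calls with quantile normalisation and cyclic loess at nearly the same fold. Smad6 stood at 0.94 with SE 0.13 as deposited, then at 0.94 and 0.95 with SE 0.13. Pmepa1 stood at 0.69 with SE 0.09, then at 0.67 with SE 0.10 in both. Nearness to the threshold alone does not account for Pmepa1. Cxcr4 lay as near as deposited (limma adjusted p = 0.0257 against 0.0253) and kept its call in both. The cause was not tested. A test that finds falls less often than rises could still leave no falls among the calls. In simulated data falls of log2 1 were recovered 1.01 times as often as rises, but the simulated shifts and the two-sided test were symmetric and held no compression of dim probe sets, so whether falls were missed stays open. This concerns the absence of falls, not the rises.

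Of the 10 splits of the 6 samples into groups of 3, 1 called as many genes as the real one, itself (17), and the highest other called 2; 10 splits are too few for a share under 0.05. For the lists, 6 splits called at least the real 3, and the highest other called 9; these splits too are too few. The other 5 of those 6 splits kept 2 of the 3 pairs of a number together, which points to the structure by number described above. Among the 4 splits that part all 3 pairs, the real one called 17 genes (29 with the block) and 3 lists, and the other three called 0 genes, 0 with the block, and 2, 0 and 0 lists.

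Several genes known from the cornified envelope of skin were highest in replicate 1. They were chosen after their values were seen, and no list of such genes was fixed or tested for enrichment. Loricrin averaged 7.51, 6.64 and 6.26 in replicates 1, 2 and 3 (adjusted p = 0.0126), Sprr1a 7.29, 6.32 and 5.98 (adjusted p = 0.00329), and Lce1g 5.95, 5.18 and 5.26 (adjusted p = 0.0129). Lce1h passed as well (adjusted p = 0.0490), and Lce1c did not (adjusted p = 0.0540). Keratinocytes could have come with the cells of that mouse and would bring their abundant transcripts. A list of 12 of these, fixed before the test, differed between replicate 1 and the others by 0.073 (BMP6) and -0.00114 (vehicle), and Krt5 and Krt14 stood at 5.68 and 5.33 in BMP6 replicate 1 against 5.78 and 5.57 in BMP6 replicate 2. This argues against keratinocytes rich in these 12 transcripts as a contaminant. Krt5 and Krt14 had low values, however, and differences of dim probe sets are compressed, so a small share of such cells is not excluded. The design names nothing else that sets replicate 1 apart, and no explanation beyond contamination was tested.

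Among genes just short of the threshold were Sertad1 (log2 fold change 0.63, adjusted p = 0.0576), Csrnp1 (0.61, 0.0675), Sik1 (0.71, 0.0703), Bhlhe41 (0.62, 0.0703) and Gadd45g (0.68, 0.0776), chosen after their values were seen and each past it with the replicate block. Relatives of called genes, also chosen after their values were seen, did not pass. The log2 fold change was 0.39 for Id4 and 0.46 for Smad9, against 0.07, 0.10, 0.08, 0.01 and 0.0047 for Smad1 to Smad5. It was 0.33, 0.42, -0.10, 0.04 and -0.14 for Dlx1, Dlx3, Dlx4, Dlx5 and Dlx6, -0.18 and -0.03 for Snai2 and Snai3, and 0.07 for Gadd45a. Of the 12867 probe sets without a symbol 0 passed in limma, with a lowest adjusted p of 0.799 and 465 (3.61%) at an unadjusted p under 0.05. Of the 1730 further probe sets of genes with more than 1, 0 passed, with a lowest adjusted p of 0.374 and 33 (1.91%) under 0.05. Among genes of the naming rule only Fdft1 had a further probe set, at a log2 fold change of -0.07 (SE 0.15).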
